A study of Mus musculus with 6 samples.

How the data were processed

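Gene expression was measured on Illumina bead arrays in the ventromedial hypothalamus of mice aged 16 weeks. Per the labels, 3 RNA pools came from control mice homozygous for a floxed Sirt1 allele and 3 from mice that also carried Sf1-Cre, which deletes Sirt1 in neurons that express SF1 (the product of Nr5a1). The background was mixed. The number of mice in each pool and their sex are not given in the sources used here, so p-values measure the spread between these pools. Per the labels' protocols, RNA was extracted with Trizol, cleaned and treated with DNase on a column, checked on a Bioanalyser, and made into biotinylated cRNA.

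The main table holds, per the file headers, a mean signal and a detection p-value for each of 45281 probes on each array. The signal is a bead intensity on a linear scale as deposited. It was not background-subtracted, since the lowest signal per array lay between 104.0 and 111.6, and not scaled between arrays, since the medians differed. The detection p-value, per the file headers, is given for each probe and array. A second table deposited by the authors holds intensity values that share a median of 134.4 and a maximum of 41225 in all 6 columns, so they were quantile normalised on a linear scale. Their rank correlation with the raw signal of the same pool was 1.000 and with that of any other pool at most 0.937. The target distribution of that table and the scanner software are not given in the sources used here, and the table served as an alternative only. No table column was left without a sample.

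Of the probes, 34885 had 1 gene symbol in the platform annotation supplied with the data, 18 had several and 10378 had none. Gene IDs of 34807 of the 34903 annotated probes were found in the RefSeq annotation of GRCm38.p6, which was used for names and for the order of neighbouring genes, and no symbol had to be changed. No genome build is named in the files, so no coordinates are given.

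In R 4.3.3 with limma 3.58.1, signals were background-corrected with normexp using the detection p-values, an offset of 16 was added, and arrays were quantile normalised and log2 transformed (neqc). Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept (20402 probes). A gene was represented by its probe with the highest mean. Probes without a single symbol were each kept as a feature. This gave 14221 features, of which 11049 were named genes and 3172 were unnamed probes. Groups were compared with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method over all features. Fold changes are SIRT1 deletion over control on the log2 scale with the offset, which compresses the changes of dim probes. Where a probe was not above background on all 3 arrays of the dimmer group, brighter over dimmer is given as "at least N-fold": the bright group's mean against the mean, per array, of the higher of the lowest detected signal and the probe's own. For single values an exact two-sided permutation test was run, whose smallest p with 3 against 3 pools is 0.1. The number of arrays limits the precision.

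Gene lists were fixed before the data were examined: 34 lists of pathways, cell types, tissues next to the ventromedial nucleus and chromosomal neighbours of Nr5a1. The 33 lists with 5 or more measured genes were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry. Another 7 lists, of exocrine pancreas, pancreatic islets, liver, stomach and intestine, salivary gland, skeletal muscle and white fat, were written after the main result was seen. Named genes followed a rule set at the same time as the first lists: Sirt1 and Nr5a1, then in each direction the 10 genes with the largest change at adjusted p under 0.05, filled to 10 with the genes of lowest p, given as values, and up to 4 members of lowest p of each list. Genes named outside that rule are identified as chosen after their values were seen.

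The procedure was tested on simulated data with the means and the eBayes-moderated variances of the 14221 features, in 20 simulations of SIRT1 deletion against control with 200 changed genes, 50 for each fold size. The test recovered 7.3% of genes changed 1.25-fold, 74.3% of those changed 1.5-fold, 99.1% of those changed 2-fold and 99.9% of those changed 3-fold. On average 10.5 of its 150.8 calls were false. With no gene changed it called 0.3 features on average. These simulations drew the genes independently of each other with normal noise of the moderated variances, so their rates may be optimistic for the real arrays. A list of 20 genes shifted by 0.3 was called in 100% of simulations.

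Alternatives covered the background correction, offset, normalisation, probe filter, probe-to-gene rule, variance prior, array weights, replicate number as a block, threshold, list test and each pool left out in turn. A block for the chip was not run, because the column names show no chip. Python 3.11.15 with matplotlib 3.10.9 drew the figures.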

Results

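The study asked how gene expression in the mouse ventromedial hypothalamus differs when Sirt1, a NAD-dependent deacetylase, is deleted in SF1 neurons. It compared 3 control pools with 3 SIRT1 deletion pools, each hybridised to 1 array. Between 20053 and 20611 of the 45281 probes per array were detected. The median raw signal was 147.5 ± 1.99 (SD, n = 3) in control and 141.2 ± 0.881 (SD, n = 3) in SIRT1 deletion pools, so the control arrays were brighter before normalisation. Correlations between arrays (across features, which are not independent replicates) lay between 0.991 and 0.995, and at most 0.00221% of probes held the same signal in any pair of arrays. The first principal component took 34.2% of the variance and set SIRT1 deletion 2 and 3 apart from the other 4 pools, with SIRT1 deletion 1 on the side of the controls.

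No difference in Sirt1 itself was detectable between the groups. The 1 probe for Sirt1 had a log2 intensity of 7.69 ± 0.11 (SD, n = 3) in control and 7.65 ± 0.13 (SD, n = 3) in deletion pools, a difference of -2.32% with a 95% interval from -16.9% to 14.9% (limma). The exact permutation p was 0.9. The position of this probe relative to the floxed segment is not given in the sources used here and part of the cells carry Cre, so the value checks neither the deletion nor the labels. Its sign turned positive without control 1 (0.027) and without SIRT1 deletion 3 (0.039). Nr5a1, which encodes SF1, had a log2 fold change of 0.45 (95% interval 0.16 to 0.73) with all 3 deletion pools above all 3 control pools, but did not pass over all features (limma adjusted p = 0.427). The Nr5a1 probe was detected on all 6 arrays but was dim, with a control mean of 5.05. The lowest detected value per array lay between 4.86 and 4.90. A second Nr5a1 probe, detected on 1 array, gave 0.30.

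Of 14221 features, 15 differed at a limma adjusted p under 0.05, 8 of them higher and 7 lower in SIRT1 deletion pools, and 19 at 0.10. The 15 comprised 3 named genes and 5 unnamed probes that were higher, and 6 named genes and 1 unnamed probe that were lower. Of the unnamed probes that were higher, 2, each detected on 1 of the 3 control arrays, had log2 fold changes of 2.23 and 1.94, which rest in part on values not above background, and 3, not above background in any control pool, were at least 1.41-fold, 2.04-fold and 2.99-fold higher. The lower unnamed probe had -1.37. In 8 of the 15 the dimmer group was not above background on any array, so their p-values rest in part on the spread of background values. For Gm5409, the SD was 0.013 in deletion and 0.207 in control pools. At an unadjusted p under 0.05 there were 1254 features, 655 higher and 599 lower, where chance gives 711. That number is 5% of the features and gives no spread. Other splits of the 6 pools into 3 against 3 gave from 397 to 1515. The features at unadjusted p under 0.05 numbered 742 without control 2 and 2009 without SIRT1 deletion 1. Without control 1, control 3 or SIRT1 deletion 1, 4 features were lower in each case, and without control 2 or SIRT1 deletion 3, 5 were higher in each case. The split was 8 higher and 11 lower with an offset of 50, and 8 higher and 12 lower when that offset was combined with normexp without negative controls. The calls numbered 4 (2 higher, 2 lower) with detection on all 6 arrays at p under 0.01, 9 (5 higher, 4 lower) without a filter, and 29 (12 higher, 17 lower) with an intensity trend and robust prior.

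The named genes that were higher were 4930555G01Rik, Rnd3 and Nr6a1. 4930555G01Rik, a RIKEN cDNA gene, was not above background in any control pool and was at least 4.56-fold higher in the deletion pools (adjusted p = 8.13e-05). That bound holds for the main processing. Over the alternatives the log2 difference of this gene, against values at background, ranged from 0.86 to 2.53. Rnd3 rose from 6.18 ± 0.10 to 7.50 ± 0.20 (SD, n = 3 pools each), a log2 fold change of 1.32 (95% interval 1.05 to 1.58, limma adjusted p = 0.0035). Over the alternatives its size ranged from 0.65, without background correction, to 1.42. Nr6a1, an orphan nuclear receptor gene next to Nr5a1 on chromosome 2, rose by 0.80 on the log2 scale (95% interval 0.58 to 1.02, adjusted p = 0.0299), but its call was lost when any 1 of the 6 pools was left out, and its adjusted p ranged up to 0.148 over the alternatives, with a size from 0.39, without background correction, to 0.84. Among 7 further genes with the lowest p in this direction, none passed (adjusted p between 0.12 and 0.169): Amhr2 (0.62), Ppcdc (0.57), Adamtsl2 (0.68, detected on 2 of 3 control arrays), Tvp23a (0.53) and Fam107a (0.46), given as log2 fold changes, and Npw, which encodes neuropeptide W, and Ptprg. The probes that represent Npw and Ptprg were not above background in any control pool, and their values were at least 1.32-fold and at least 1.51-fold higher. Fam107a passed in 5 of 19 alternatives (adjusted p from 0.0108 to 0.535) and Ptprg in 1 of 18, without SIRT1 deletion 1 (0.0305, range to 0.55). Amhr2, the receptor of anti-Muellerian hormone, has 2 more probes, neither detected on any array, and another detected Ptprg probe gave 0.23.

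The 6 named genes that were lower belong to a list of exocrine pancreas genes written after the calls were seen. Zg16, a zymogen granule protein, was at least 2.70-fold lower (adjusted p = 0.0035). Try4 and Try5, which are trypsinogens, were at least 2.03-fold (adjusted p = 0.00359) and at least 1.69-fold lower (adjusted p = 0.0035), and the trypsinogen-like pseudogene Gm5409 at least 1.40-fold lower (adjusted p = 0.0416). Cela2a, an elastase, fell by 1.34 on the log2 scale (95% interval -1.73 to -0.95, adjusted p = 0.0352). Reg1 fell by 1.05 (-1.35 to -0.75, adjusted p = 0.0349). The call of Cela2a was lost without any 1 control or without SIRT1 deletion 1, that of Reg1 without any 1 control or without SIRT1 deletion 1 or 2, and that of Gm5409 without control 1, control 3 or any 1 deletion pool (adjusted p up to 0.237, 0.202 and 0.259 over all alternatives). Cela2a passed in 11 of 18 alternatives, Reg1 in 7 of 17 and Gm5409 in 4 of 17. All of these calls were also lost without a filter, with every probe a feature and under the replicate block. Over the alternatives the size of Cela2a ranged from -1.50 to -0.96 and that of Reg1 from -1.18 to -0.31, both smallest without background correction. The smallest log2 sizes of Zg16, Try4, Try5 and Gm5409 were -0.51, -0.36, -0.29 and -0.23. These are smaller than the bounds above, which hold for the main processing. Zg16, Try4, Rnd3 and 4930555G01Rik passed in every alternative that kept their probe. Try5 passed in 16 of 17 and failed without background correction (limma adjusted p = 0.110). Probes of Try4, Try5 and Gm5409 can share sequence. The 4 lowest p among the rest were those of Cel (-0.72), Clps (-1.11), Cpa1 (-1.37) and Pnliprp1 (-0.82), a lipase, colipase, a carboxypeptidase and a lipase-related protein, with adjusted p between 0.0645 and 0.169. Cpa1 was detected on 1 of the 3 deletion arrays, so its value rests in part on values not above background. Clps passed in 6 of 18 alternatives (adjusted p from 0.00305 to 0.401), among them without SIRT1 deletion 2 (0.0252). Cpa1 passed in 5 of 17 (0.0108 to 0.441) and Pnliprp1 in 2 of 18 (0.0237 to 0.491), each also without SIRT1 deletion 3 (0.0184 and 0.0365), and Cel in 1 of 18 (0.0417 to 0.301).

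**Figure D1:**
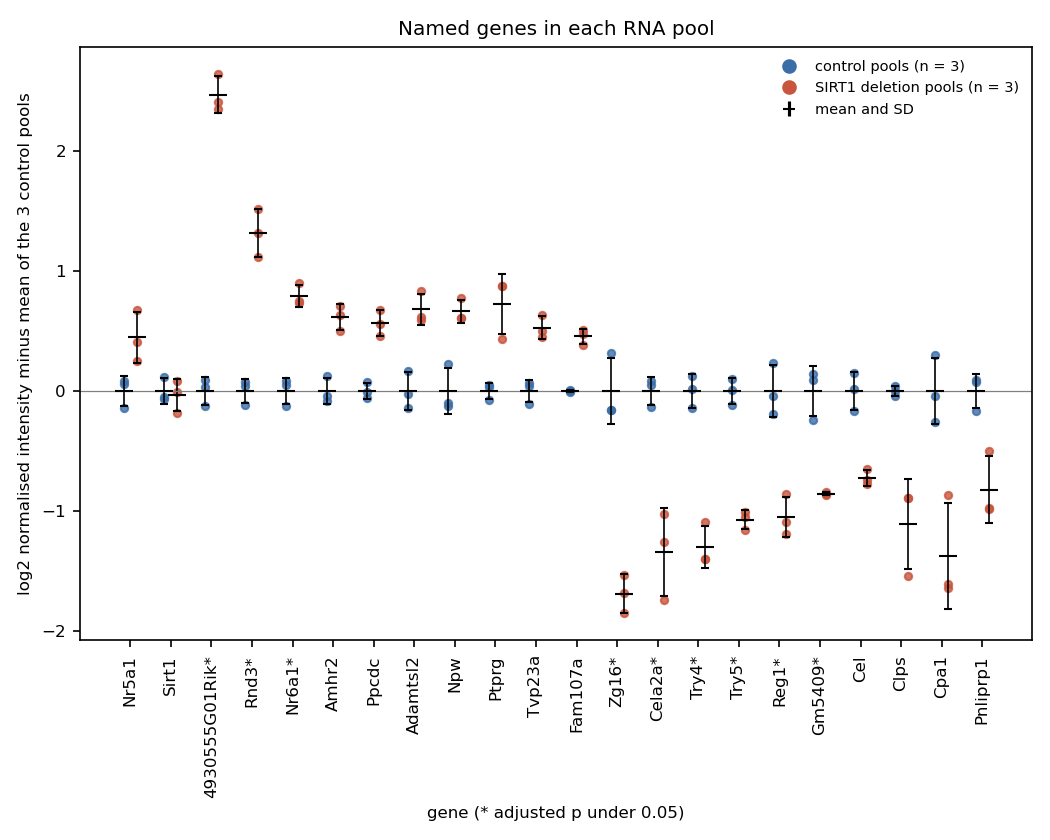
Log2 normalised intensity of each named gene in each RNA pool, minus the mean of the 3 control pools; points are pools, black bars the mean and SD of each group (n = 3), asterisks mark adjusted p under 0.05. Genes such as Rnd3 (1.32) and Cela2a (-1.34) separate the groups, while Sirt1 (-0.03) does not.

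Of that list of exocrine pancreas genes 26 were measured, of which 24 were lower, 20 at an unadjusted p under 0.05, with a median log2 fold change of -0.77 (-0.54 with the 7 members undetected in all deletion pools at their bounds). Its camera adjusted p over the added lists was 1.55e-29, and 0.022 with an estimated correlation. All 6 named genes called lower belong to it (Fisher's exact test, one-sided, p = 9.12e-17, among 11049 genes), which is not independent evidence because the list was made around them. Of the 20 members that were not called, 18 were lower and 14 passed an unadjusted p under 0.05, with a median of -0.50 (camera p = 6.29e-18, p = 0.0118 with an estimated correlation). These members, Cel, Clps, Cpa1 and Pnliprp1 among them, were also listed after the main result was seen, so they are not independent evidence either. Both small camera p-values assume an inter-gene correlation of 0.01, where the estimates were 0.217 for the 26 genes and 0.190 for the 20. The 7 members undetected in all deletion pools passed the detection filter through the control pools alone. The pools of the 2 groups did not overlap, deletion being lower, in 20 of the 26 genes, where chance gives 5% for that direction and 7.21% of all features did so. Without this list's genes, 9 features passed. A second detected probe of Amy2a5, an amylase named after its values were seen, gave -0.05 against -0.47 for the first.

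Of the 34 lists fixed beforehand, the meninges and fibroblasts list was the only one past a camera adjusted p of 0.05. Of its 14 measured genes 13 were lower (median -0.51, adjusted p = 0.0081). However, no member reached an unadjusted p under 0.05 by the probe that represents it, and with an estimated correlation the adjusted p was 0.924. Its lowest p were those of Dcn (-0.37), Slc22a6 (-0.65), Igfbp2 (-0.55) and Fbln1 (-0.46), which encode matrix, transport and secreted proteins. Without control 2 these values were -0.24, -0.35, -0.27 and -0.22, and each moved by over 1.5 times without at least 1 other pool. The list's mean log2 intensity was 6.66, 8.01 and 7.58 in controls 1 to 3 and 6.64, 7.45 and 6.60 in SIRT1 deletion 1 to 3, so that the groups overlapped, and the call was lost without control 2 (adjusted p = 0.336), control 3 (0.168), SIRT1 deletion 1 (0.176) or SIRT1 deletion 3 (0.302), over a range from 2.01e-10 to 0.924 in all alternatives. Slc22a6 was detected on 2 control arrays and 1 deletion array, and Igfbp2 on 2 arrays of each group. Other detected probes gave -0.25, -0.10 and -0.025 for Fbln1, -0.36 for Igfbp2 and -0.41 for Dcn. In a limma fit of all probes, this Dcn probe had an unadjusted p of 0.0216, and the others did not reach 0.05.

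Immediate early genes, which neurons express on activation, missed the threshold: 18 of 24 were lower (median -0.13, camera adjusted p = 0.0506, 0.924 with an estimated correlation). Fos (-0.58), Npas4 (-0.33) and Arc (-0.34) had p of 0.0156, 0.0347 and 0.0496, and none passed when adjusted over the list alone. Without SIRT1 deletion 3 Fos had -0.36. The list passed under 11 of 21 alternatives, among them without control 1 (adjusted p = 0.0162) and without SIRT1 deletion 2 (8.77e-06), and its adjusted p reached 0.924.

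**Figure D2:**
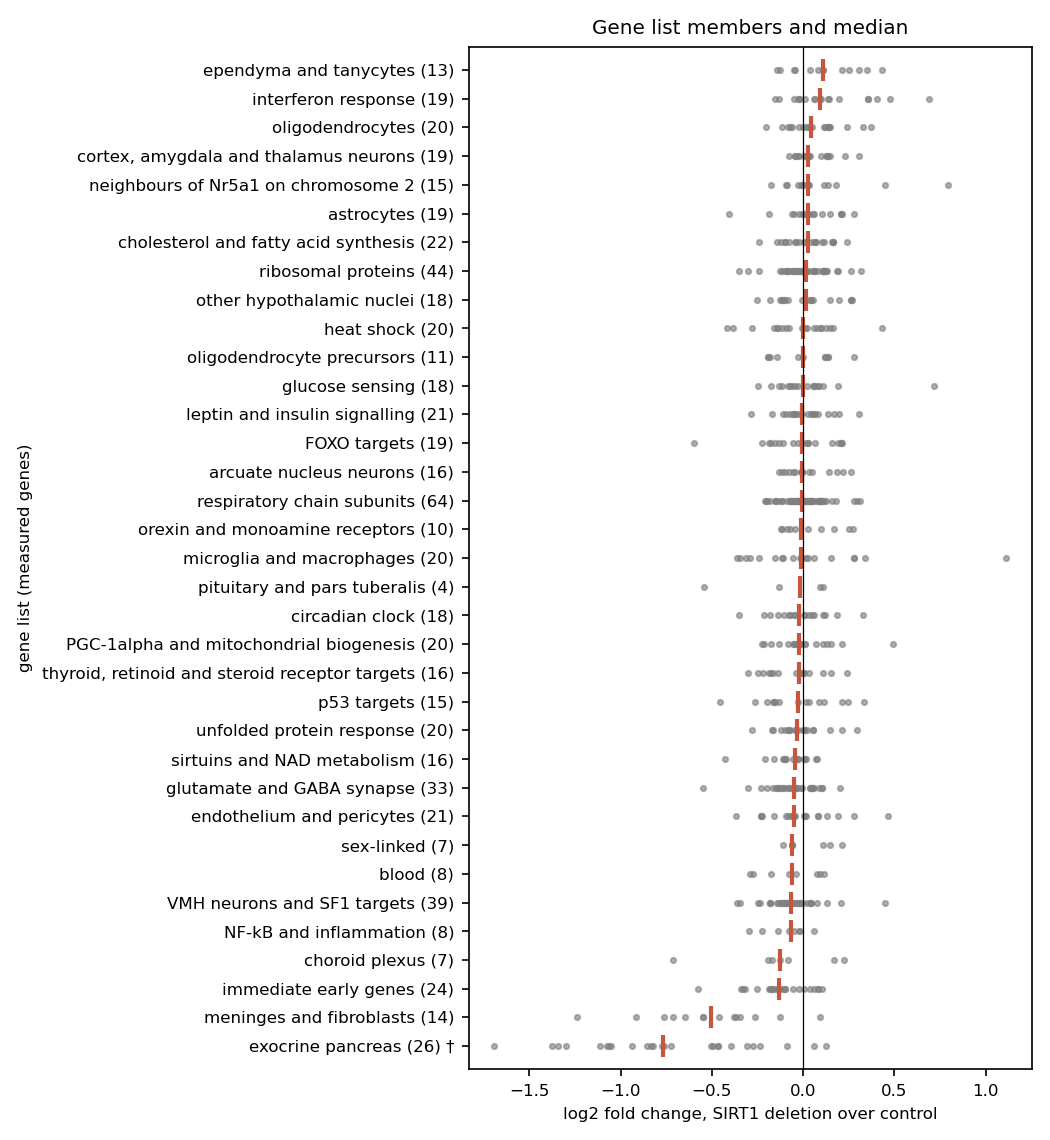
Log2 fold change, SIRT1 deletion over control, of each measured gene (grey points) and the median (red bar) of each list, with the number of measured genes in brackets; the dagger marks the list written after the calls were seen. The exocrine pancreas (-0.77) and meninges (-0.51) lists lie apart from the rest.

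Markers of ventromedial neurons and SF1 targets were lower in 31 of 39 measured genes (median -0.06, camera adjusted p = 0.249), and 0 passed adjusted over the list alone. Sox14 (-0.36) and Tnfrsf11b (-0.34) had p of 0.005 and 0.00605, and Tac1 had -0.18. Nr5a1 itself, a member of the list, went the other way (0.45, adjusted p = 0.0834 over the list alone). The list passed without control 1 (adjusted p = 0.0486, up to 0.924 in the alternatives). Clock genes did not shift together as a list (9 of 18 higher, median -0.02, camera adjusted p = 0.887). Opposite changes of members would cancel in that test. For this list fry's test for change in either direction gave an adjusted p of 0.547. Cry2 had 0.33 and Dbp -0.18. The sirtuin and NAD list had 11 of 16 lower (adjusted p = 0.32), with Nnmt, which methylates nicotinamide, at -0.43 and Sirt6 at -0.21. Glutamate and GABA synapse genes had 23 of 33 lower (adjusted p = 0.287), with Gabbr2 at -0.30 and Gria1 at -0.23, though 3 other detected Gria1 probes did not follow (0.06, 0.00 and 0.09). Orexin and monoamine receptor genes were 5 higher and 5 lower (adjusted p = 0.874), Htr1a at 0.25 and Drd2 at 0.17. Leptin and insulin signalling genes were 10 higher and 11 lower (adjusted p = 0.874), with Pik3ca at -0.28. The Stat5a probe was not above background in any control pool and its value was at least 1.05-fold higher, while a second Stat5a probe, detected on 1 array, gave -0.0030 on the log2 scale. Of 18 glucose-sensing genes 9 were higher (adjusted p = 0.874), and Nos1, which makes nitric oxide, passed adjusted over the list alone (log2 fold change 0.72, adjusted p = 0.0107) but not over all features (0.206). Over all features Nos1 passed in 1 of 19 alternatives, the intensity trend and robust prior (limma adjusted p = 0.019). The other detected probe of Nos1 gave -0.17, and Ldhb had -0.25. Several of these values rested on single pools. Tac1 had -0.10 without control 3, Gria1 -0.15 without SIRT1 deletion 2 and Pik3ca -0.19 without SIRT1 deletion 3. The log2 difference of Stat5a, against values not above background, was 0.30 with all pools and 0.17 without control 3. Sirt6 had -0.094 without SIRT1 deletion 2 and -0.35 without SIRT1 deletion 1, and Htr1a 0.16 without control 2 and 0.40 without control 3. Other detected probes gave -0.23 for Nnmt and -0.12 for Sirt6, and Gabbr2 was detected on 2 of 3 deletion arrays.

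Metabolic and stress lists did not pass. PGC-1alpha and mitochondrial biogenesis (adjusted p = 0.874; Opa1 0.49, Sod2 -0.22), respiratory chain subunits (0.897; Uqcrh 0.30, Atp5e 0.31), FOXO targets (0.874; Cat -0.60, Gabarapl1 0.21), cholesterol and fatty acid synthesis (0.874; Idi1, not above background in any deletion pool, at least 1.06-fold lower) and ribosomal proteins (0.828; Rps2 -0.30, Rpl30 0.32, a second detected Rps2 probe 0.05) had medians within 0.03 of 0, and 0 members of each passed adjusted over the list alone. In the p53 list (adjusted p = 0.615) Plk2, a kinase, passed adjusted over the list alone (-0.46, adjusted p = 0.0382) and Mdm2 had -0.26. NF-kB and inflammation genes were lower in 7 of 8 (0.287; Nfkbia -0.30) and interferon response genes higher in 13 of 19 (median 0.09, adjusted p = 0.225; Oasl2 0.47, B2m 0.35). The interferon list passed in 4 of 21 alternatives, among them without SIRT1 deletion 1 (adjusted p = 0.00936, up to 0.924 in the others). Unfolded protein response (0.828; Calr 0.30, Atf4 -0.28), heat shock (0.874; Dnaja1 -0.42, Dnajb4 0.43, Hspa1a -0.38) and thyroid, retinoid and steroid receptor targets (0.615; Rxra -0.22) did not pass. Other detected probes of Atf4 (0.03) and Dnajb4 (-0.16) had the other sign. The median and mean had opposite signs for PGC-1alpha, respiratory chain, leptin and insulin, glucose sensing, orexin, arcuate, heat shock, oligodendrocyte precursor, microglia and sex-linked genes, all near 0. Camera's direction followed the mean except for PGC-1alpha and microglia, where it followed the median. Without control 2 Uqcrh had 0.17 and Nfkbia -0.18, and without SIRT1 deletion 2 Atp5e had 0.19 and Oasl2 0.26. Atf4 had -0.18 without control 1, and Hspa1a -0.25 without control 1 or SIRT1 deletion 3. Another detected Mdm2 probe gave -0.12.

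Markers of other cells did not pass either, apart from the meninges list. Arcuate (adjusted p = 0.874; Trh 0.26), other hypothalamic nuclei (0.874; Hcrt -0.25), cortex, amygdala and thalamus (0.305; Foxp1 0.23), astrocytes (0.767; Slc4a4 -0.41), oligodendrocytes (0.287; 13 of 20 higher; Trf 0.24, Mog 0.37, Ugt8a 0.33), oligodendrocyte precursors (0.956; C1ql1 0.28), microglia and macrophages (0.874; Mrc1 -0.31, Aif1 0.34, Siglech -0.36, C1qb 0.28), ependyma and tanycytes (0.249; Crym 0.43, Rax 0.35), choroid plexus (0.828; Igf2 -0.71, which was -0.36 without control 2, -1.14 without control 1 and -1.09 without SIRT1 deletion 2), blood (0.615; Hbb-b2 -0.29) and sex-linked genes (0.874; Kdm5c 0.21) had no member past the threshold adjusted over the list alone. A second detected probe of Siglech gave 0.12 and one of Kdm5c -0.27. The sex-linked list joins genes of the X and Y chromosomes, so opposite changes would cancel in camera. For that list fry's test for change in either direction gave an adjusted p of 0.679. The ependyma list passed without SIRT1 deletion 1 (adjusted p = 0.0163, up to 0.924 in the other alternatives). In the endothelium and pericyte list (0.897) Slco1a4, a transporter of the blood-brain barrier, passed adjusted over the list alone (0.46, adjusted p = 0.0472) and Pdgfrb had 0.28. Of the 4 measured pituitary genes, too few for the list test, Gh passed adjusted over the list alone (-0.54, adjusted p = 0.0485), and had -0.36 without SIRT1 deletion 3. Single pools moved several of these values. Without SIRT1 deletion 2 Ugt8a and Rax each had 0.18, without SIRT1 deletion 3 C1ql1 had 0.17 and C1qb 0.19, and without control 2 Crym had 0.28. Without SIRT1 deletion 1 Slc4a4 had -0.61 and Hbb-b2 -0.18, and without control 1 Kdm5c had 0.14. Hcrt had -0.15 without control 1 and -0.41 without control 3. C1ql1 and Rax were detected on 1 control array, Mrc1 on 1 deletion array and Gh on 2 deletion arrays. Other detected probes gave 0.18 for Aif1 and 0.47 for Foxp1.

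The 15 measured genes of the list of Nr5a1 and its neighbours on chromosome 2 did not shift as a list (camera adjusted p = 0.305), but fry's test for change in either direction gave an adjusted p of 0.00996. Nr6a1 and Nr5a1 passed adjusted over the list alone (adjusted p = 0.000347 and 0.0481), while Dennd1a (0.18) and Ppp6c (0.13) did not. Dennd1a had 0.087 without control 2 and Ppp6c 0.078 without control 3.

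**Figure D3:**
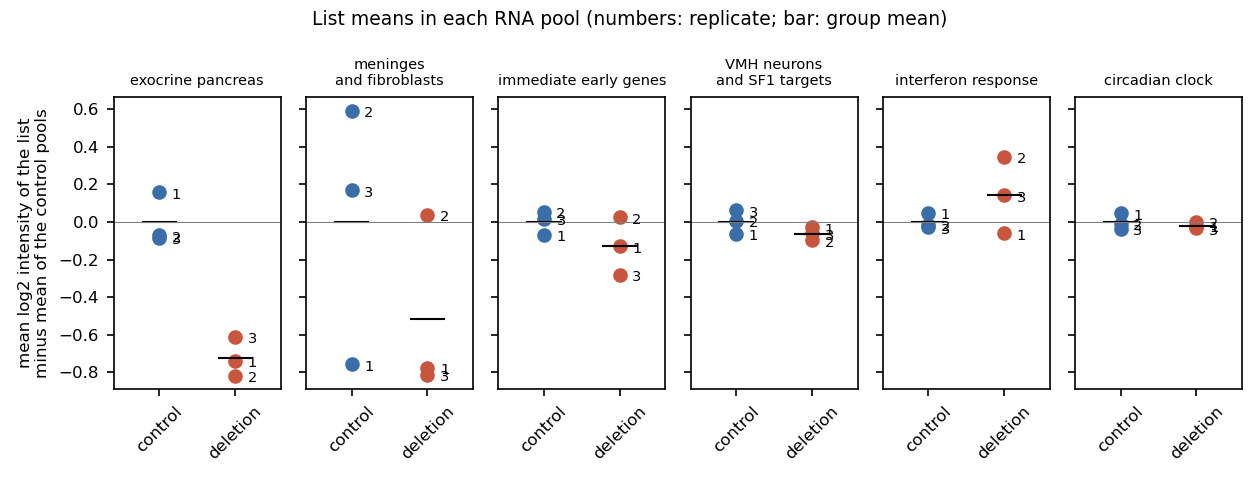
Mean log2 intensity of 6 lists in each pool, minus the mean of the control pools; numbers are replicates and bars group means. The exocrine pancreas list separates the groups, and the meninges list varies within both groups.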

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

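The tests with the meninges list mean as a covariate and without the exocrine pancreas genes were chosen after seeing the data; the others were planned. The cause of each difference was not tested unless fewer genes or pools explain it by construction. Signal over background limits the dim calls, since 8 of the 15 were undetected in a whole group. The strict filter changed 2 choices together, detection on all 6 arrays and a detection p under 0.01.

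Counts at adjusted p under 0.05 (main 15, 8 higher, 7 lower) were 9, 5 and 4 without a filter, with 2264 at unadjusted p under 0.05; 4, 2 and 2 with the strict filter; and 29 with 17 lower under the intensity trend and robust prior. Lower calls were 11 under offset 50, 12 under offset 50 with normexp without negative controls, 4 with every probe a feature. With the meninges covariate 5 were higher; without exocrine pancreas genes 9 passed, 1 lower. The replicate block gave 10 calls, 4 lower. Across all features, same-numbered pools did not deviate together (r = -0.0515, -0.0443 and -0.023). No pairing by number was visible, but 3 pools per group cannot exclude it. The mean of the meninges list was highest in replicate 2 of both groups (8.01 in control, 7.45 in SIRT1 deletion). Leaving out 1 pool gave 10 to 14 calls, 5 to 6 higher, 4 to 9 lower, and 742 to 2009 at unadjusted p under 0.05; Sirt1 ranged from -0.092 to 0.039. The chip block was not run.

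Lists past adjusted p 0.05 (main 1) numbered 2 under offset 50 with normexp without negative controls (both changed), offset 50 alone, the series matrix, the trend, the replicate block and without exocrine pancreas genes; 3 with no filter, the strict filter and array weights; 0 with an estimated correlation, fry and the meninges covariate (whose own list then has no value); and 0 to 3 leaving out a pool. Immediate early genes passed (median) under normexp with offset 50 (-0.086), series matrix (-0.079), offset 50 (-0.094), no filter (-0.11), strict filter (-0.15), trend and replicate block (-0.13 each), weights (-0.13) and without exocrine pancreas genes (-0.13); interferon response under no filter (0.081), strict filter (0.14) and weights (0.12). The meninges list (-0.51) lost its call with an estimated correlation and under fry.

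The direction of the list test turned, with none of these past the threshold, as follows (medians, which need not change sign). Under normexp with offset 50 it turned for oligodendrocyte precursors (4.3e-05). Under no background correction it turned for respiratory chain subunits (-0.0086), oligodendrocyte precursors (4.0e-05). Under 75th percentile scaling it turned for respiratory chain subunits (-0.054), leptin and insulin signalling (-0.043), ribosomal proteins (-0.042), astrocytes (-0.028), oligodendrocyte precursors (-0.056). Under series matrix values it turned for respiratory chain subunits (-0.0080), oligodendrocyte precursors (0.00017). Under offset 50 it turned for oligodendrocyte precursors (-9.6e-06). Under no filter on dim probes it turned for the gene Stat5a (-0.0030), respiratory chain subunits (-0.0090), leptin and insulin signalling (-0.0078), glucose sensing (-0.014), orexin and monoamine receptors (0.0012), sex-linked (-0.059). Under the strict filter it turned for circadian clock (0.0052), leptin and insulin signalling (-0.017), other hypothalamic nuclei (-0.083), oligodendrocyte precursors (-0.014). Under every probe its own feature it turned for circadian clock (-0.0020), glucose sensing (-0.053). Under the trend it turned for oligodendrocyte precursors (-8.2e-06). Under array quality weights it turned for respiratory chain subunits (-0.014). Under the meninges covariate it turned for PGC-1alpha and mitochondrial biogenesis (0.0091), respiratory chain subunits (-0.024), FOXO targets (-0.0011), orexin and monoamine receptors (-0.050), ribosomal proteins (-0.010), arcuate nucleus neurons (-0.022), oligodendrocyte precursors (0.015), microglia and macrophages (-0.015), endothelium and pericytes (-0.011), blood (0.051). Leaving out 1 pool, medians ranged -0.080 to -0.039 (VMH neurons and SF1 targets), -0.037 to 0.013 (circadian clock), -0.038 to 0.017 (PGC-1alpha and mitochondrial biogenesis), -0.030 to 0.021 (respiratory chain subunits), -0.028 to 0.017 (FOXO targets), 0.024 to 0.16 (interferon response), -0.018 to 0.017 (leptin and insulin signalling), -0.027 to 0.042 (glucose sensing), -0.044 to 0.085 (orexin and monoamine receptors), -0.19 to -0.029 (immediate early genes), -0.060 to -0.028 (unfolded protein response), -0.045 to 0.033 (heat shock), -0.0086 to 0.031 (ribosomal proteins), -0.055 to 0.032 (arcuate nucleus neurons), -0.021 to 0.070 (other hypothalamic nuclei), -0.054 to 0.083 (oligodendrocyte precursors), -0.16 to 0.030 (microglia and macrophages), -0.074 to -0.0088 (endothelium and pericytes), 0.059 to 0.14 (ependyma and tanycytes), -0.83 to -0.23 (meninges and fibroblasts), -0.086 to 0.035 (sex-linked). Of the values of named genes under the alternatives 1515 kept direction and side of the threshold, 21 passed it newly, 41 no longer passed and 1 turned; of those of lists 607 kept both.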

Other observations

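Of the tests here, the splits of the pools for gene lists were chosen before their result was seen; all other tests of explanations, and the exocrine pancreas and other tissue lists, were chosen after.

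Other tissue lists gave no like pattern, but they cannot show that the pattern is confined to the pancreas. Few of their genes were measured, and some are also on lists of brain cells. Of the liver list, Trf is also on the oligodendrocyte list and Ttr, named after its values were seen, on the choroid plexus list. Of the islet list 2 genes were measured, Sst and Slc30a8, with a median of 0.00 (-0.00436); Sst is also made in the hypothalamus. Liver (7 measured, 5 lower, median -0.19, limma camera adjusted p = 0.600), stomach and intestine (4, 0.02), salivary gland (3, 0.31) and white fat (4, 0.10) were too few or showed no shift. Serpina1a of the liver list and Gkn3 of the stomach list, both lower and chosen after their values were seen, passed adjusted over their lists alone. Serpina1a was not above background in any deletion pool and was at least 1.03-fold lower. Skeletal muscle genes were higher in 4 of 6 (median 0.23, camera adjusted p = 0.0404 over the added lists, adjusted p = 0.209 with an estimated correlation). Among microglial genes Fcer1g, chosen after its values were seen, had the widest range, from 4.67 in control 1 to 7.99 in SIRT1 deletion 2.

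The mean log2 intensity of the exocrine pancreas list was 5.45, 5.37 and 5.58 in SIRT1 deletion 1 to 3 and 6.35, 6.12 and 6.11 in controls 1 to 3. Sequence shared between trypsinogen probes is argued against as the whole cause, because the 22 other members had a median of -0.61. Of these, 16 were lower at an unadjusted p under 0.05. They include Zg16, Cela2a and Reg1, the calls that the list was written around. The bootstrap interval of the median, -0.94 to -0.40, resampled genes as if independent, so it leaves out the spread between pools. Pancreas RNA carried over in unequal amounts is a candidate explanation: within groups the 26 genes deviated together (mean pairwise correlation 0.217), above the highest of 10000 expression-matched random lists (0.212), though co-regulated genes would do so too. Besides the meninges list, the value was also higher for heat shock (0.225), interferon response (0.243), ependyma and tanycytes (0.260), liver (0.267) and blood (0.442). The other tested lists lay lower. The value of the 26 genes is thus not particular to carried-over RNA. The brightest probes, which need not mark the most abundant transcripts, were those of Amy2a5 (11.6 in control, 11.1 in deletion), named after its values were seen, and Cela2a (8.96 and 7.62); 22 of the 26 were detected in all control and 11 in all deletion pools, 1 is on another list, and 14 genes with a probe, Prss2 and Ctrc among them, were not measurable. An effect of the deletion cannot be told apart from handling by group, since 20 of 26 genes separated the groups and any difference in handling would too.

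Nr6a1 was higher, and its neighbour Nr5a1 had a higher mean that did not pass over all features. Gene copies brought in with the Sf1-Cre transgene cannot be told apart from other causes: the lower 95% bound of Nr5a1, 0.1625, only restates the pattern, and the transgene's extent is not given in the sources used here. A linked chromosome segment of another strain cannot be told apart: 3 of the 20 nearest measured genes, 10 on each side, had p under 0.05 where 1.71 would be met by the share over all genes (one-sided binomial p = 0.241). Rnd3 and Adamtsl2, with higher values, and Cel, with lower values, are also on chromosome 2 but not among those 20. The genes 4930555G01Rik, Ptprg and Fam107a, all with higher values, are on chromosome 14. Whether any of these genes is linked to a difference between the groups was not tested. The groups also differ in Cre itself, and an effect of the deletion itself stays open and was not tested.

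The meninges and fibroblasts list was lower on average but uneven. Unequal amounts of meninges in the pools is a candidate explanation: its 14 genes deviated together within groups (mean pairwise correlation 0.805, highest random list 0.386), though co-regulated genes would do so too. Its brightest probes were those of Igf2 (10.9 in control, 10.2 in deletion) and Ptgds (10.6 and 9.82), the latter named after its values were seen, 10 of 14 were detected in all pools of each group, and Igf2 is also on the choroid plexus list. An effect of the deletion cannot be told apart with 3 pools each; the list mean had an exact two-sided permutation p of 0.2.

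The 6 pools form 10 splits of 3 against 3, too few for a share under 0.05. The real split called 15 features, a number that only it reached among the 10, and the highest other called 7. At an unadjusted p under 0.05 it gave 1254, and 2 splits, the real one included, gave as many or more. The highest other gave 1515, for control 1 with SIRT1 deletion 2 and 3 against the rest, the split that exchanges control 1 and SIRT1 deletion 1. The real split put 1 list past the threshold. Of the 10 splits, 9, the real one included, put at least 1, the highest other giving 8.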
